A study of Arabidopsis thaliana with 4 samples.

How the data were processed

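Total RNA from shoots of 7-day-old Arabidopsis thaliana seedlings was sequenced by the authors in 4 samples, 1 per group: Col-0 and a line labelled hfr1 pil1, each in white light and in low R:FR. Per the labels, plants grew on sugar-free agar at 22 °C in continuous white light of 30 to 50 µE per m2 and s with an R:FR of 1.2, and the low R:FR light held 13 µE of red, 1.23 of blue and 20 of far-red. A 1 h treatment that the labels mention was not analysed here.

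The deposited table holds a normalized signal for 33558 loci in 4 columns, which the authors made by dividing read counts by 1 factor per library. Bowtie and TAIR10 are named in the submitters' processing notes, and their versions, the counting tool and the tool behind the factors are not given in the sources used here. Per the file headers the Col-0 columns are means. Every mutant value was a whole multiple of 1 step, within a tolerance of 0.01 reads, and the Col-0 values were sums of whole multiples of 2 steps, from which 2 libraries per Col-0 mean were recovered. The recovered size factors were 1.26 and 0.834 (Col-0 white light), 1.63 and 1.28 (Col-0 low R:FR), 1.30 (hfr1 pil1 white light) and 0.723 (hfr1 pil1 low R:FR), with 11442048, 7556437, 13765680, 11062781, 14684713 and 7358583 reads in this order. The Col-0 read totals leave out the genes that could not be split, while the mutant totals are complete, so the size factors compare depth better. The split failed for 74 and 83 genes of the Col-0 columns, all at or above 13334 and 10196 normalized counts, which hold 20.6% and 18.0% of those columns, so that many photosynthesis genes have no test. In all, 33459 genes had 6 libraries. Tested on simulated data, 33492 of 33558 genes were split, all of them rightly. With both steps 10776 of 10776 Col-0 white light values under 100 were solved, and 940 (8.72%) with the second step 1% off.

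The plan, made before the data were examined, took the labels' 1 library per group, so that it had no test, and expected CPM, RPKM or counts, with a filter and a pseudocount of 1. The table holds normalized counts instead, so that unit was set to 10.8 normalized counts, which scales the mean column total as CPM does. A gene entered with a mean of at least 10.8 normalized counts (20111 genes), the log2 ratio was taken after adding 10.8 normalized counts, and a gene counted as higher or lower at a log2 ratio of at least 1. The comparisons were low R:FR against white light in each genotype, hfr1 pil1 against Col-0 in each light, and the difference of the responses.

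The tests were added after the data were seen. Recovered reads of 20012 genes (99 could not be tested) were fitted with edgeR 4.0.16 in R 4.3.3, with the authors' size factors, a quasi-likelihood test, 6 libraries and 2 residual degrees of freedom. The biological coefficient of variation was 0.0525 and the prior degrees of freedom were 10.7. Benjamini-Hochberg adjusted p under 0.05 was called. Each lone mutant library was assumed to vary like the Col-0 libraries. On simulated data with 100 changed genes per fold, 94% of 2-fold and 99% of 4-fold changes were recovered for the Col-0 response. For the hfr1 pil1 response it was 93% of 4-fold changes. Of 2-fold changes it was 69% between genotypes in low R:FR and 55% for the difference of the response. False calls were 10 of 203, 7 of 195, 5 of 74 and 5 of 60 calls in this order of comparisons. The simulation gave all genes and libraries 1 common dispersion, so it takes the assumption above as given and may overstate recovery.

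The 24 gene lists, fixed before the values were seen, were shade-induced regulators, auxin synthesis and transport, auxin response, cell wall loosening, gibberellin, brassinosteroid, photoreceptors and light signalling, light-harvesting and photosystem subunits, chlorophyll synthesis, senescence and sugar starvation, flavonoid and anthocyanin, salicylic acid and immunity, jasmonate, glucosinolate, flowering, circadian clock, cold, drought and abscisic acid, heat shock, iron deficiency, phosphate starvation, cell division, root markers, seed storage and late embryo markers, and reference transcripts. Of 462 entries 5 were dropped because the reference names the locus otherwise, and 9 without a name there were kept. Each list's median was ranked among 10000 random lists of its size matched in 20 bins of expression, and a percentile under 1 or over 99 was called apart. Of 120 list comparisons 73 were apart. Independent lists of unrelated genes would give 2.4, which is no fair measure of chance here. Members of a list may move together, lists share genes, and the comparisons share libraries. A second root list of 20 genes was written later for 1 test.

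Named genes followed a rule of the plan. HFR1 and PIL1 came first. In each comparison the 10 highest and 10 lowest log2 ratios followed, among genes with a symbol and a mean of at least 54.2 normalized counts, 5 times the filter, without organelle genes. Up to 4 members of each list with the largest absolute log2 ratio were added. Gene names came from the TAIR10.1 annotation, which holds 32825 of the loci. Its coordinates were not used, since the build differs from the submitters'.

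The other settings chosen in the plan were a pseudocount 0.1 times as large, no filter, a filter at 54.2 normalized counts, median-ratio rescaling, and nuclear genes rescaled to 1 total. Another unit in the table was to be tried as well and was not, because the table holds none. Added later were rescaling to the column total, leaving out each Col-0 library, edgeR with TMM scaling, DESeq2 1.42.0, an edgeR call with a 2-fold change, and thinning all libraries to the depth of the shallowest. Counting intervals are exact conditional binomial intervals at 95% and cover counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.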

Results

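RNA was sequenced from shoots of 7-day-old Arabidopsis thaliana seedlings of 2 genotypes, the accession Col-0 and a line whose labels name mutations in both HFR1 and PIL1. HFR1 and PIL1 are basic helix-loop-helix proteins of the shade response. Seedlings stayed in continuous white light for 7 d, or were moved after 3 d of white light to 96 h of low R:FR. This is light with a low ratio of red to far-red, the light signal of shade by neighbouring plants. Per the labels it held 13 µE of red and 1.23 of blue, against 30 to 50 µE of white light. The amount of light thus changed together with R:FR, and these libraries cannot tell the 2 apart. Responses to low R:FR below are responses to this light as a whole. The labels list 4 samples, 1 per combination of genotype and light. The deposited table gave read counts per gene divided by 1 factor per library, in 4 columns with totals of 11427477 (Col-0 white light), 10433887 (Col-0 low R:FR), 11309567 (hfr1 pil1 white light) and 10171547 (hfr1 pil1 low R:FR). Each Col-0 column was the authors' mean, and its values resolved into whole reads of 2 libraries, so that 6 libraries of at least 7358583 reads could be tested. The 20111 genes with a mean of at least 10.8 normalized counts were compared. A log2 value followed by ± is edgeR's fitted log2 fold change with an approximate standard error (SE). That SE is the absolute log2 fold change divided by the square root of the test's F statistic. It can be narrower than counting error where reads are few. Other log2 values, unless a fit or reads are named beside them, are ratios of deposited values after adding 10.8 normalized counts, which understates the change of low genes. "Rose" and "fell" are kept for genes called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Genes named only to spell out a count were chosen after their values were seen.

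Each genotype had few libraries. Both mutant columns held 1 library, which the test assumed to vary like Col-0, and nothing says whether the 2 Col-0 libraries of a condition came from separate plants. The p-values therefore measure only the spread between libraries, which may be technical. The 2 Col-0 libraries of a condition differed by more than sampling noise, with a chi-square per gene of 2.43 in white light and 2.59 in low R:FR where sampling alone gives 1. The SD of their log2 difference was 0.21 and 0.18 over 20012 genes.

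HFR1 (AT1G02340) and PIL1 (AT2G46970) were not lower in the libraries labelled hfr1 pil1. In white light HFR1 stood at 22.2 and 33.6 normalized counts in the 2 Col-0 libraries and at 189 in the library labelled hfr1 pil1 (2.81 ± 0.21 SE, adjusted p = 2.14e-05 by edgeR with Benjamini-Hochberg adjustment). In low R:FR it stood at 2046 and 2359 in Col-0 and at 2112 in the mutant library (-0.06 ± 0.10 SE, edgeR, Benjamini-Hochberg adjusted p = 0.869). PIL1 stood at 12.7 and 20.4 in Col-0 white light and at 220 in the mutant white light library (3.79 ± 0.25 SE, edgeR, Benjamini-Hochberg adjusted p = 8.92e-06). In low R:FR it stood at 241 and 313 in Col-0 and at 1574 in the mutant library (2.52 ± 0.12 SE, edgeR, Benjamini-Hochberg adjusted p = 4.6e-07). Both transcripts rose under low R:FR in Col-0, by 6.35 ± 0.14 for HFR1 and 4.11 ± 0.22 for PIL1 (SE). They also rose in the mutant libraries, by 3.48 ± 0.14 and 2.84 ± 0.16 (SE). The transcript levels do not check the genotype labels, since a mutated gene can still be transcribed. Every direction drawn from the mutant libraries below rests on their labels, and "hfr1 pil1" means the library labelled so.

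**Figure D1:**
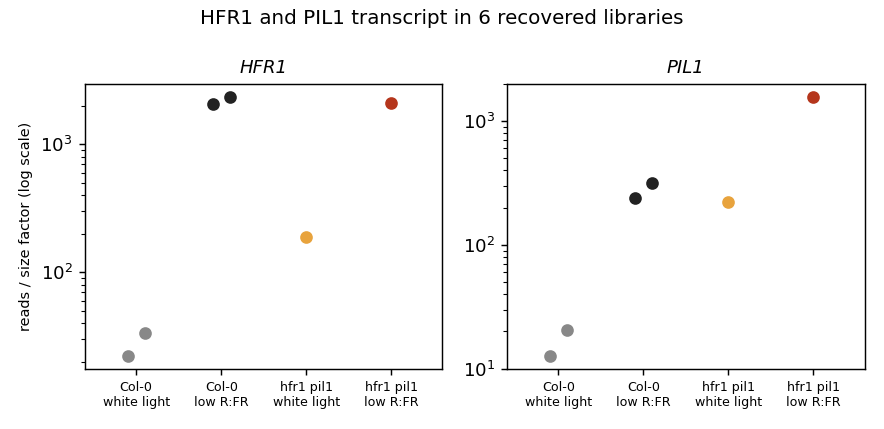
HFR1 and PIL1 in the 6 recovered libraries, as reads divided by the size factor on a log axis, with 1 point per library and colour for the group. HFR1 lies at 22.2 and 33.6 in Col-0 white light, at 189 in hfr1 pil1 white light and between 2046 and 2359 in the 3 low R:FR libraries, and PIL1 reaches 1574 in hfr1 pil1 low R:FR.

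The first comparison asks what changed after 96 h of low R:FR in Col-0 samples labelled as shoots. Most shade regulators and auxin-responsive genes of the lists rose, and most anthocyanin genes fell. DIN1 (AT4G35770), a dark-inducible gene, went from 11.4 to 1504 normalized counts (7.14 ± 0.18 SE). FLP1 (AT4G31380) went from 1.60 to 288 (7.55 ± 0.26 SE), and FT (AT1G65480), the florigen, from 19.9 to 575 (4.87 ± 0.13 SE). DFR (AT5G42800), an enzyme of anthocyanin synthesis, went from 2607 to 40.0 (-6.01 ± 0.15 SE). Among the other genes ranked highest were ATPMEPCRD (AT2G43050; 4.29 ± 0.14 SE), GAT1_2.1 (AT1G15040; 4.13 ± 0.19 SE), the branched-chain aminotransferase gene BCAT-2 (AT1G10070; 4.29 ± 0.16 SE), the thionin gene THI2.2 (AT5G36910; 3.79 ± 0.11 SE) and CYP71A20 (AT4G13310; 5.27 ± 0.31 SE). Among those ranked lowest were NUDT24 (AT5G19470; -6.71 ± 0.17 SE), MES18 (AT5G58310; -5.74 ± 0.20 SE) and GASA5 (AT3G02885; -6.03 ± 0.20 SE). Adjusted p for these 12 genes lay between 3.5e-11 for DIN1 and 2.47e-08 for CYP71A20 (edgeR, Benjamini-Hochberg).

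Of 18 shade-induced regulators, 15 rose and none fell, and 16 rose when adjusted over the list alone (ATHB4, HAT3 and PIF6 did not pass over all genes). ATHB2 (AT4G16780), a homeodomain transcription factor used as a shade marker, went from 68.0 to 492 normalized counts (2.90 ± 0.13 SE, edgeR, Benjamini-Hochberg adjusted p = 2.3e-09). ST2A (AT5G07010), a hydroxyjasmonate sulfotransferase, went from 42.8 to 742 (4.09 ± 0.13 SE). Of 29 measured auxin-responsive genes, 28 rose, also when adjusted over the list alone, and the exception was GH3.1 at -0.12. IAA29 (AT4G32280) went from 7.37 to 394 (5.75 ± 0.21 SE) and the ethylene synthesis gene ACS8 (AT4G37770) from 2.39 to 77.6 (4.97 ± 0.33 SE). SAUR19 (AT5G18010) and SAUR22 (AT5G18050) rose by 5.02 ± 0.38 and 4.07 ± 0.26 (SE), as members of a family of close copies whose counts may be mixed. Among 14 genes of auxin synthesis and transport, 9 rose and 2 fell, with the same counts adjusted over the list alone. The auxin synthesis gene YUC8 (AT4G28720) rose by 2.78 ± 0.18 and the efflux carrier gene PIN3 (AT1G70940) by 1.03 ± 0.070 (SE), while TAA1 (AT1G70560), which acts upstream of the YUC enzymes, fell (-1.11 ± 0.11 SE).

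Of 18 brassinosteroid genes, 16 rose and none fell, with the same counts adjusted over the list alone. The synthesis genes BR6OX1 (AT5G38970; 2.35 ± 0.20 SE) and CPD (AT5G05690; 1.24 ± 0.067 SE) were among them. Of 21 tested cell wall loosening genes, 12 rose and 4 fell, the same counts as adjusted over the list alone. XTH24 (AT4G30270) rose by 2.65 ± 0.073 (SE) and XTH31 (AT3G44990) fell (-2.30 ± 0.073 SE). XTH4 (AT2G06850) was not tested because its value could not be split into libraries, and it stood at 1762 and 10835 normalized counts. Of 18 gibberellin genes, 9 rose and 4 fell, over all genes and adjusted over the list alone. GASA6 (AT1G74670), a gibberellin-regulated gene, rose by 2.31 ± 0.099 (SE), and the synthesis gene GA3ox1 (AT1G15550) fell (-1.88 ± 0.18 SE). Of 27 photoreceptor and light signalling genes, 11 rose and 5 fell, also adjusted over the list alone, with the transcription factor gene PIF4 (AT2G43010) at 144 and 978 normalized counts (2.77 ± 0.087 SE) and HYH (AT3G17609), a homologue of HY5, at 339 and 164 (-1.05 ± 0.093 SE). Of 18 flowering genes, 10 rose and 1 fell, also adjusted over the list alone. FT was followed by SOC1 (AT2G45660), a floral integrator, at 2.36 ± 0.11 (SE).

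All 24 flavonoid and anthocyanin genes changed, with 23 lower and 1 higher both over all genes and adjusted over the list alone. LDOX (AT4G22880; -5.32 ± 0.15 SE), TT19 (AT5G17220; -5.48 ± 0.12 SE) and UF3GT (AT5G54060; -5.72 ± 0.18 SE) fell, as did DFR, and 5MAT (AT3G29590), UGT75C1 (AT4G14090) and TT7 (AT5G07990) lay at -5.75, -4.81 and -4.69 in the same edgeR fit. The gene that rose was MYBL2 (AT1G71030), known as a repressor of anthocyanin synthesis, at 1.63 ± 0.12 (SE). Of 16 chlorophyll synthesis genes, 13 fell and 1 rose (GLK2, 0.32), with the same counts adjusted over the list alone. PORC (AT1G03630) went from 2724 to 1179 normalized counts (-1.21 ± 0.070 SE) and HEMA1 (AT1G58290) from 2183 to 981 (-1.15 ± 0.082 SE). Of 44 light-harvesting and photosystem genes only 14 could be tested, of which 13 fell and LHCB1.4 rose, also adjusted over the list alone. Over all 44 the median log2 ratio was -0.45, against -0.29 for random lists matched on expression (percentile 0.53). At least 2-fold lower were 7 of the 44, and 1 was 2-fold higher. LHCB4.3 (AT2G40100) went from 1483 to 106 (-3.82 ± 0.084 SE). LHCB and RBCS genes are close copies, so that single members are uncertain.

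Genes of sugar starvation and senescence went both ways, with 10 of 20 higher and 4 lower, the same adjusted over the list alone. DIN6 (AT3G47340), an asparagine synthetase, rose by 3.23 ± 0.14 and DIN10 (AT5G20250) by 2.95 ± 0.091 (SE), while SAG29 lay at -1.66. Of 15 cold, drought and abscisic acid genes, 13 rose and 2 fell (KIN1 and HAI1), over all genes and adjusted over the list alone. COR15A (AT2G42540) rose by 1.45 ± 0.15 and NCED3 (AT3G14440), an enzyme of abscisic acid synthesis, by 1.66 ± 0.19 (SE). Of 15 tested jasmonate genes, 7 fell and 4 rose, or 8 and 4 adjusted over the list alone. AOC2 (AT3G25770), an enzyme of jasmonate synthesis, fell from 3832 to 781 normalized counts (-2.30 ± 0.086 SE). Of 13 root markers, 4 rose and 3 fell, also adjusted over the list alone. Of 19 glucosinolate genes, 10 fell and 2 rose, also adjusted over the list alone, with CYP79F2 (AT1G16400) at -1.86 ± 0.091 and MYB51 (AT1G18570), a regulator of indole glucosinolates, at 1.99 ± 0.18 (SE). Of 13 salicylic acid and immunity genes, 3 rose and 3 fell, or 3 and 4 adjusted over the list alone. CBP60G (AT5G26920) rose by 1.79 ± 0.23 and PR5 (AT1G75040), a pathogenesis-related gene, fell (-1.72 ± 0.24 SE). Among the 3 that fell was ICS1, which did not pass without Col-0 white light library 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0606, against 0.00164 with it, at a log2 ratio of -0.64).

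In all, 963 genes were at least 2-fold higher and 561 at least 2-fold lower in Col-0 low R:FR. The test on recovered reads called 4602 higher and 5056 lower of 20012. Both low R:FR libraries lay beyond both white light libraries in 9648 of these 9658 genes, which selection by the same libraries nearly fixes. Over all tested genes it was 74.5%, where chance gives 33.3% for equally noisy libraries. Counts of called list members are to be read against the calls over all genes. By median, photoreceptors and light signalling, salicylic acid and immunity, glucosinolate, iron deficiency and cell division were not apart from random lists. Nor were root markers, seed storage and late embryo markers, and reference transcripts. DESeq2 did not call 10 of the 96 named genes called here, and leaving out 1 Col-0 library lost 8 of these calls. The share of higher genes rested on the scaling: it was 63.2% of the 2-fold set as deposited, 73.8% with columns rescaled to their total (1211 higher, 430 lower) and 73.6% with nuclear genes rescaled to 1 total (1200 higher, 430 lower), as these scalings moved the median gene by up to 0.14 on the log2 scale in the 2 responses.

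**Figure D2:**
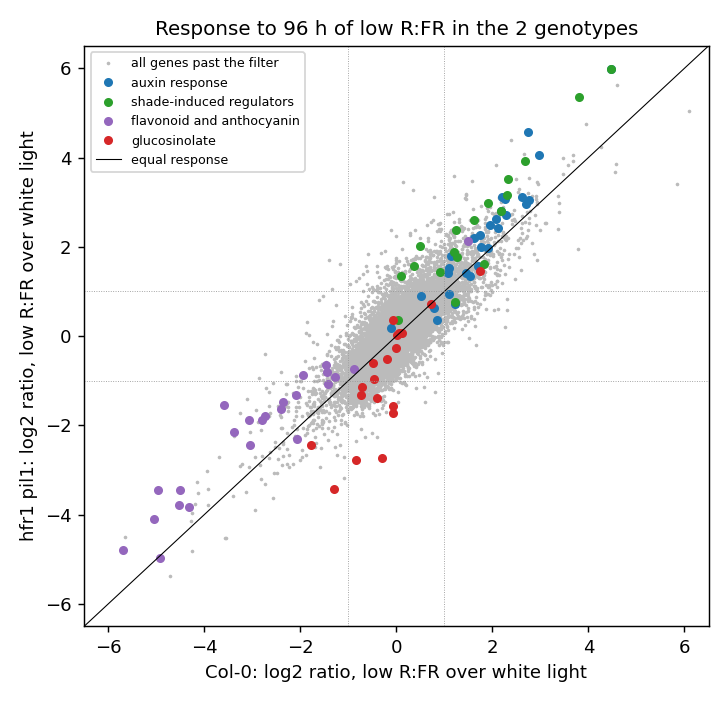
Log2 ratio of low R:FR over white light in Col-0 (x axis) and in hfr1 pil1 (y axis) for the 20111 compared genes, with members of 4 lists in colour, dotted lines at a 2-fold change and a diagonal of equal response. Flavonoid and anthocyanin genes lie at the lower left (list medians -2.77 and -1.84), auxin-responsive genes at the upper right (1.76 and 2.19), and part of the glucosinolate genes well below the diagonal.

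The second comparison asks the same of the libraries labelled hfr1 pil1. IAA29 went from 4.62 to 963 normalized counts (7.67 ± 0.28 SE), FLP1 from 0.770 to 563 (9.33 ± 0.33 SE), ST2A from 40.8 to 2105 (5.69 ± 0.17 SE) and ACS8 from 1.54 to 285 (7.43 ± 0.38 SE). The white light levels of FLP1 and ACS8 rest on 1 and 2 reads, so their folds carry a wide counting error. At the other end UF3GT went from 547 to 6.91 (-6.28 ± 0.36 SE), FTM1 (AT1G43800) from 363 to 5.53 (-6.01 ± 0.55 SE), the sucrose synthase gene SUS4 (AT3G43190) from 497 to 23.5 (-4.40 ± 0.48 SE) and GSTF14 (AT1G49860) from 445 to 22.1 (-4.33 ± 0.38 SE). Adjusted p for these 8 genes lay between 1.74e-09 for ST2A and 1.2e-05 for SUS4 (edgeR, Benjamini-Hochberg).

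The lists moved as follows in hfr1 pil1. Of 18 shade-induced regulators, 17 rose, also adjusted over the list alone, with ATHB2 at 60.8 and 1080 normalized counts (4.15 ± 0.17 SE). Of 29 auxin-responsive genes, 26 rose, also adjusted over the list alone. Of 14 genes of auxin synthesis and transport, 10 rose and 2 fell, also adjusted over the list alone, with YUC8 at 4.06 ± 0.23 and YUC9 (AT1G04180) at 2.42 ± 0.27 (SE). Flavonoid and anthocyanin genes again fell, 22 of 24 with MYBL2 higher, over all genes and adjusted over the list alone. Of 13 root markers, 5 rose and 2 fell, also adjusted over the list alone. Of 16 chlorophyll synthesis genes, 14 fell and 1 rose, and of 14 tested light-harvesting and photosystem genes 12 fell and none rose, with the same counts adjusted over the list alone. Of 19 glucosinolate genes, 12 fell and 3 rose, or 13 and 3 adjusted over the list alone, with BCAT4 (AT3G19710) going from 1629 to 141 (-3.53 ± 0.20 SE) and CYP79F1 (AT1G16410) from 996 to 140 (-2.83 ± 0.16 SE). Of 15 cold, drought and abscisic acid genes, 14 rose and none fell, also adjusted over the list alone, with the dehydrin gene RAB18 (AT5G66400) going from 182 to 1085 (2.58 ± 0.13 SE). Brassinosteroid genes rose in 16 of 18 cases, cell wall loosening genes rose in 13 and fell in 6 of 21, both also adjusted over the list alone, and gibberellin genes rose in 9 and fell in 3 of 18, or 10 and 3 adjusted over the list alone. Adjusted p for the 6 genes named here with their SE lay between 8.49e-09 for ATHB2 and 1.7e-05 for YUC9 (edgeR, Benjamini-Hochberg).

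By size 1304 genes were at least 2-fold higher and 918 lower, and edgeR called 3676 higher and 3706 lower. By median, photoreceptors and light signalling, salicylic acid and immunity, heat shock and iron deficiency were not apart from random lists in hfr1 pil1. Nor were root markers, seed storage and late embryo markers, and reference transcripts. DESeq2 did not call 16 of the 89 named genes called here. The 2-fold set was 58.7% higher as deposited, 71.6% with columns rescaled to their total (1658 higher, 657 lower) and 71.9% with nuclear genes rescaled to 1 total (1656 higher, 646 lower). The 2 responses share no library, and they shared 705 genes at least 2-fold higher where independent sets give 62.4, and 377 lower where independent sets give 25.6. Of the 2-fold higher genes, 73.2% of those in Col-0 and 54.1% of those in hfr1 pil1 were in the shared set, and of the lower ones 67.2% and 41.1%. In opposite directions there were 3 genes lower in Col-0 and higher in hfr1 pil1, and 0 the other way. Across genes, which are not independent replicates, Pearson's r of the 2 responses was 0.831 and Spearman's rho 0.788. The mutant ratio compares 1 library with 1, so its exact binomial interval covers counting error only: for HFR1 (1528 against 246 reads, with nothing added) the 95% interval of 3.48 ran from 3.28 to 3.68. With every library thinned to the shallowest depth, single Col-0 library pairs gave 957 to 1165 genes higher and 624 to 718 lower, and hfr1 pil1 gave 1354 and 934.

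The third comparison asks how the genotypes differed after 96 h of low R:FR. In the library labelled hfr1 pil1, 12 of 18 shade-induced regulators were called higher and 7 of 19 glucosinolate genes lower. ST2A stood at 742 normalized counts in Col-0 and 2105 in hfr1 pil1 (1.51 ± 0.096 SE), ATHB2 at 492 and 1080 (1.14 ± 0.11 SE) and ACS8 at 77.6 and 285 (1.87 ± 0.16 SE). CYP79F1, which starts the conversion of chain-elongated methionine to glucosinolates, stood at 662 and 140 (-2.25 ± 0.15 SE). BCAT4 and MAM1 (AT5G23010), which act in methionine chain elongation, stood at 602 and 141 (-2.10 ± 0.20 SE) and at 2020 and 746 (-1.44 ± 0.12 SE). MYB29 (AT5G07690), a transcription factor of this pathway, stood at 78.9 and 16.6 (-2.24 ± 0.42 SE). Adjusted p for these 7 genes lay between 2.96e-06 for ST2A and 0.0133 for MYB29 (edgeR, Benjamini-Hochberg).

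Other genes at the top of the ranking were ORP4C (AT5G57240) at 56.1 and 256 normalized counts (2.21 ± 0.21 SE), the fatty acyl reductase gene FAR1 (AT5G22500) at 404 and 1352 (1.74 ± 0.086 SE) and the lipid transfer protein genes LTP2 (AT2G38530) at 1172 and 3276 (1.48 ± 0.078 SE) and LTP3 (AT5G59320) at 81.2 and 239 (1.52 ± 0.23 SE). CHS (AT5G13930), chalcone synthase, stood at 846 and 2628 (1.63 ± 0.097 SE), and the iron superoxide dismutase gene FSD1 (AT4G25100) at 171 and 463 (1.41 ± 0.24 SE). CYP707A2 (AT2G29090), which degrades abscisic acid, stood at 20.2 and 63.6 (1.62 ± 0.31 SE), a call lost without Col-0 low R:FR library 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0533). At the bottom were LHCB1.4 (AT2G34430) at 7989 and 1703 (-2.23 ± 0.12 SE), the aspartate kinase gene AK3 (AT3G02020) at 502 and 167 (-1.59 ± 0.18 SE), CDEF1 (AT4G30140) at 677 and 268 (-1.33 ± 0.12 SE) and BCB (AT5G20230) at 125 and 42.9 (-1.55 ± 0.24 SE). XTH22 (AT5G57560), a touch-induced cell wall gene, stood at 861 and 418 in the 2 Col-0 libraries and at 199 in hfr1 pil1 (-1.70 ± 0.37 SE). Adjusted p for these 12 genes lay between 4.6e-07 for FAR1 and 0.032 for XTH22 (edgeR, Benjamini-Hochberg). PHI-1 (AT1G35140) did not pass (-2.12 ± 0.54 SE, edgeR, Benjamini-Hochberg adjusted p = 0.0599).

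Of 18 shade-induced regulators, 12 were called higher and none lower (13 and 1 adjusted over the list alone), among them YUC9 at 54.6 and 137 normalized counts. Of 14 auxin synthesis and transport genes, 3 were higher (4 and 1 lower adjusted over the list alone), namely YUC2, YUC8 and YUC9, and the call of YUC2 (0.87) was lost without Col-0 low R:FR library 1 (edgeR, Benjamini-Hochberg adjusted p = 0.168). Of 29 auxin-responsive genes, 5 were higher (8 adjusted over the list alone), and of 18 brassinosteroid genes 3 (6 adjusted over the list alone). Of 24 flavonoid and anthocyanin genes, 6 were higher and none lower (11 adjusted over the list alone): CHS, CHI, CHIL, FLS1, TT19 and MYB111. The call of MYB111 (AT5G49330), at 23.9 and 59.4 normalized counts, was lost without low R:FR library 1 or 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0505 and 0.0723). Of 19 glucosinolate genes, 7 were lower and none higher (10 adjusted over the list alone), and the other 3 were CYP79F2, CYP83A1 and AOP2 at -0.67, -0.86 and -1.18. Of 14 tested light-harvesting genes, 6 were lower and LHCB4.3 was higher (8 and 1 adjusted over the list alone), and of 16 chlorophyll synthesis genes 3 were lower (11 adjusted over the list alone). Of 13 salicylic acid genes, WRKY70 and CBP60G were lower (3 adjusted over the list alone), of 15 jasmonate genes VSP2 (2 adjusted over the list alone), and both salicylic acid calls (-0.83 and -1.09) were lost without Col-0 low R:FR library 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0624 and 0.101), that of CBP60G also without library 2 (0.131).

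By size 50 genes were higher and 70 lower, with 78 higher once Col-0 low R:FR library 1 was left out. The test called 197 higher and 280 lower. The mutant library lay outside both Col-0 libraries in these 477 genes, which selection by the same libraries nearly fixes. It did so in 76.9% of all tested genes, where chance gives 66.7% for equally noisy libraries. The mutant library was the shallowest, which by itself raises this share, so the excess is not read as an effect of genotype. DESeq2 did not call 21 of the 45 named genes called here, among them ORP4C, ACS8, LTP3, FSD1, MYB29, XTH22, BCB, YUC8 and YUC9, and of these it gave an adjusted p only for FSD1 and XTH22. Leaving out 1 Col-0 library lost 12 of these 45 calls, among them SAUR22, BEE1 and CHLI1 within the list counts above. Leaving out a library moved these calls to 322 and 457 (Col-0 white light library 1), 324 and 462 (white light library 2), 146 and 263 (low R:FR library 1) or 150 and 187 (low R:FR library 2). At 1 depth the mutant library differed by 2-fold from the Col-0 low R:FR libraries in 160 and 179 genes, and these 2 libraries from each other in 32.

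The fourth comparison asks how the genotypes differed in white light. More genes were called lower than higher in the library labelled hfr1 pil1 (379 against 115), and the genes ranked lowest included some of late embryo, drought and abscisic acid response. M17 (AT2G41260), a late embryo gene, stood at 178 normalized counts in Col-0 and 9.24 in hfr1 pil1 (-4.29 ± 0.32 SE). RAB18 stood at 701 and 182 (-1.95 ± 0.12 SE), RD29B (AT5G52300) at 196 and 64.7 (-1.58 ± 0.18 SE) and KIN1 (AT5G15960) at 483 and 138 (-1.78 ± 0.28 SE). MRN1 (AT5G42600), marneral synthase, stood at 286 and 74.7 (-1.90 ± 0.25 SE), and CYP705A12 (AT5G42580), a cytochrome P450 gene, at 187 and 37.7 (-2.25 ± 0.32 SE). Adjusted p for these 6 genes lay between 4.67e-06 for RAB18 and 0.00616 for KIN1 (edgeR, Benjamini-Hochberg). KIN1 was not called by DESeq2 (Benjamini-Hochberg adjusted p = 0.0785), unlike the other 5.

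Further genes at the bottom were MLP328 (AT2G01520; -1.84 ± 0.25 SE), PYD4 (AT3G08860; -1.73 ± 0.23 SE), OCT1 (AT1G73220; -1.99 ± 0.33 SE), ICS2 (AT1G18870; -1.59 ± 0.26 SE) and the tonoplast aquaporin gene TIP2;3 (AT5G47450; -1.81 ± 0.35 SE), with adjusted p between 0.0022 and 0.017 (edgeR, Benjamini-Hochberg). MLP328 and ICS2 were not called by DESeq2 (Benjamini-Hochberg adjusted p = 0.053 and 0.115). Among the genes ranked highest after HFR1 and PIL1 were CCL (AT3G26740) at 3331 and 5793 normalized counts (0.80 ± 0.077 SE, edgeR, Benjamini-Hochberg adjusted p = 0.000292), UMAMIT29 (AT4G01430) at 59.3 and 121 (0.99 ± 0.20 SE) and the haemoglobin gene HB1 (AT2G16060) at 377 and 654 (0.76 ± 0.18 SE), whose call was lost without Col-0 low R:FR library 1 or 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0544 and 0.055). UMAMIT29 and HB1 were not called by DESeq2 (Benjamini-Hochberg adjusted p = 0.777 and 1.0). Of 15 cold, drought and abscisic acid genes, 5 were lower and COR15B was higher (10 and 1 adjusted over the list alone). Of 15 jasmonate genes, 4 were lower (7 adjusted over the list alone), with VSP2 (AT5G24770) at 2110 and 917 (-1.20 ± 0.13 SE). Of 24 flavonoid and anthocyanin genes, 6 were lower (13 adjusted over the list alone). Of 14 tested light-harvesting genes, LHCB2.1, LHCB2.2 and LHCB2.3 were lower (4 adjusted over the list alone). None of the 18 shade-induced regulators passed edgeR, also adjusted over the list alone, although their median of -0.20 lay at percentile 0 of random lists. Tissue markers moved as well: of 13 root markers PRP3, EXPA7 and EXPA18 were lower and IRT1 higher (5 and 2 adjusted over the list alone), and the 4 seed storage and late embryo markers had a median of -1.09 with OLEO1 called lower (3 adjusted over the list alone). The call of EXPA7 (-0.94) was lost without white light library 2 (edgeR, Benjamini-Hochberg adjusted p = 0.068), and that of OLEO1 (-1.08) without white light library 1 (0.0863) or low R:FR library 1 or 2 (0.0503 and 0.0512).

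By size 7 genes were higher and 157 lower. These counts were 40 and 261 without Col-0 white light library 1 and 8 and 106 without library 2. The edgeR test called 115 higher and 379 lower, and 214 and 629 without white light library 1. The mutant library lay outside both Col-0 libraries in these 494 genes, again nearly fixed by selection, and in 73.6% of all tested genes, where chance gives 66.7% for equally noisy libraries. DESeq2 called 17 and 92 genes, and did not call 24 of the 42 named genes called by edgeR. Of these 42 calls, 8 were lost without 1 Col-0 library, among them DFR and AOC1 within the list counts above.

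**Figure D3:**
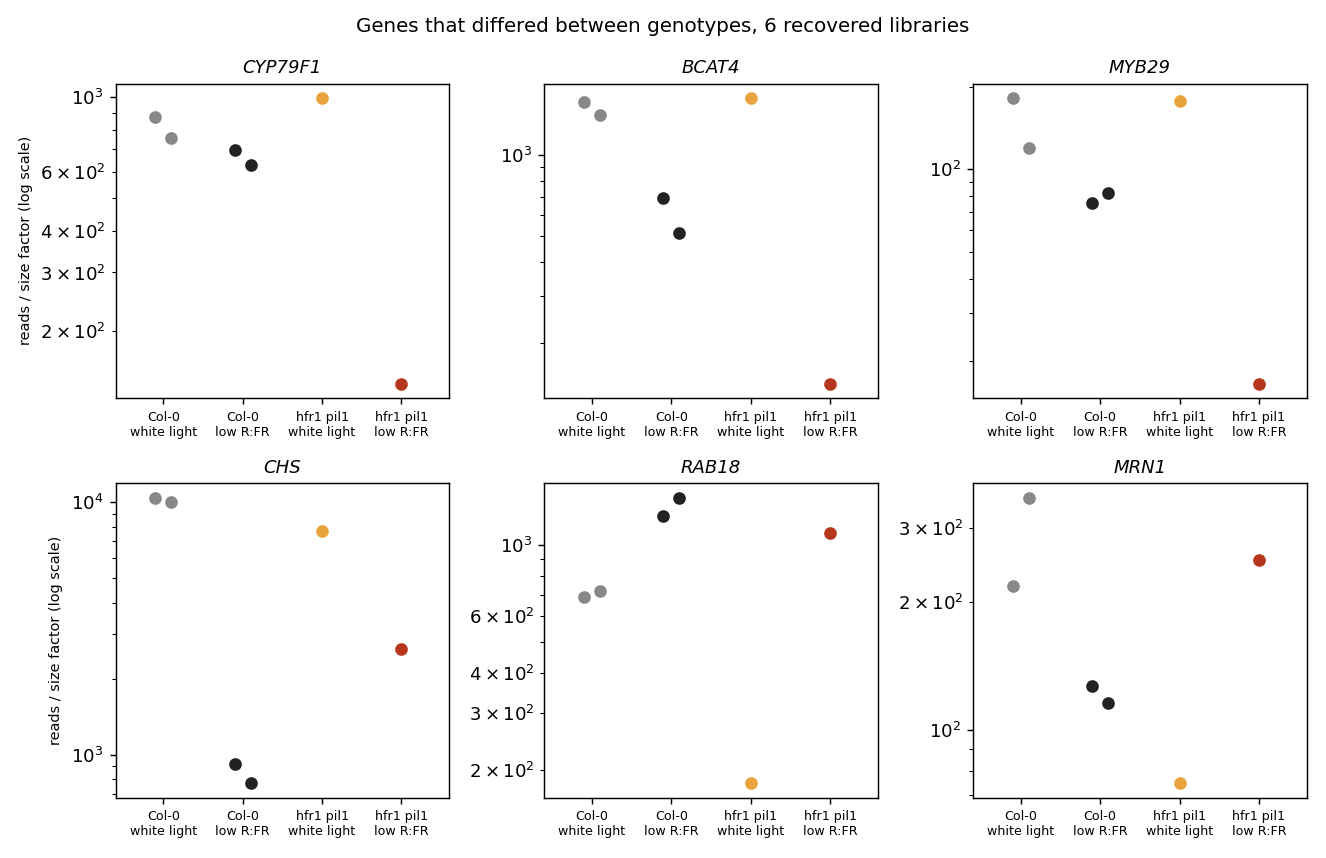
Reads divided by the size factor, on log axes, in the 6 recovered libraries for 6 genes that differed between genotypes, with 1 point per library and colour for the group. CYP79F1, BCAT4 and MYB29 are lowest in hfr1 pil1 low R:FR, RAB18 and MRN1 are lowest in hfr1 pil1 white light at 182 and 74.7, and CHS in low R:FR is higher in hfr1 pil1 (2628) than in both Col-0 libraries (771 and 920).

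The last comparison tests whether the response to low R:FR itself differed between genotypes, by an interaction term over all 6 libraries. It called a lower difference for 6 of 19 glucosinolate genes and a higher one for 9 of 24 flavonoid genes and 8 of 18 shade-induced regulators. CYP79F1 changed from 814 to 662 normalized counts in Col-0 and from 996 to 140 in hfr1 pil1, a difference of -2.53 ± 0.18 (SE). For BCAT4 it was -2.23 ± 0.24, for MYB29 -2.43 ± 0.47 and for MAM1 -1.67 ± 0.15 (SE). CHS changed from 10223 to 846 in Col-0 and from 7699 to 2628 in hfr1 pil1, a difference of 2.04 ± 0.14 (SE). ST2A (1.60 ± 0.27 SE), ATHB2 (1.25 ± 0.25 SE) and YUC9 (1.83 ± 0.35 SE) responded more strongly in hfr1 pil1. Adjusted p for these 8 genes lay between 2.03e-05 for CHS and 0.0142 for ATHB2 (edgeR, Benjamini-Hochberg).

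HFR1 itself responded less in hfr1 pil1, from its higher white light level (-2.87 ± 0.24 SE), and so did PIL1 (-1.27 ± 0.32 SE, edgeR, Benjamini-Hochberg adjusted p = 0.0451), a call lost without Col-0 white light library 1 (edgeR, Benjamini-Hochberg adjusted p = 0.195) or low R:FR library 2 (edgeR, Benjamini-Hochberg adjusted p = 0.053), and not made by DESeq2 (Benjamini-Hochberg adjusted p = 0.0642). The highest differences were those of MRN1 (2.94 ± 0.35 SE), M17 (3.41 ± 0.40 SE), CYP705A12 (2.74 ± 0.40 SE), KIN1 (2.47 ± 0.37 SE), OCT1 (2.35 ± 0.41 SE) and MLP328 (2.16 ± 0.33 SE), all of them genes with a low level in hfr1 pil1 white light. NEET (AT5G51720) and FSD1 followed at 1.99 ± 0.35 and 1.94 ± 0.30 (SE). ORP4C did not pass (1.96 ± 0.55 SE, edgeR, Benjamini-Hochberg adjusted p = 0.0731). On the lower side stood LHCB1.4 (-2.06 ± 0.15 SE), BCB (-2.36 ± 0.30 SE), CDEF1 (-1.71 ± 0.15 SE) and AK3 (-1.69 ± 0.22 SE), with adjusted p for these last 12 called genes between 2.07e-05 for LHCB1.4 and 0.00813 for NEET (edgeR, Benjamini-Hochberg). DESeq2 did not call 22 of the 44 named genes called here, among them MRN1, CYP705A12, M17, MLP328, OCT1, NEET, FSD1, BCB, MYB29 and YUC9, and of these it gave an adjusted p only for MLP328, NEET and FSD1. Of these 44 calls, 6 were lost without 1 Col-0 library, among them PAP1 within the flavonoid count below.

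Of 18 shade-induced regulators, 8 responded more strongly in hfr1 pil1 and none less (13 and 1 adjusted over the list alone). Of 24 flavonoid and anthocyanin genes, 9 had a higher difference and none a lower one (19 adjusted over the list alone), and of 19 glucosinolate genes 6 had a lower one (11 lower and 1 higher adjusted over the list alone). Of 16 chlorophyll synthesis genes, 6 had a lower difference (8 adjusted over the list alone), of which GSA1 (-0.59) and GSA2 (-0.63) were lost without Col-0 low R:FR library 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0507 and 0.0574). Of 15 cold, drought and abscisic acid genes, 5 had a higher and 1 a lower difference (8 and 1 adjusted over the list alone). None of these 15 was called between genotypes in low R:FR (list median 0.034), while the white light median was -0.40. Tissue markers differed too: the median of 13 root markers was 0.57 (percentile 99.99), with 1 called higher and 2 lower (6 and 3 adjusted over the list alone), and that of 4 seed storage and late embryo markers was 0.77 (percentile 99.63), with none called by edgeR (2 higher adjusted over the list alone). None of 29 auxin-responsive genes passed edgeR over all genes or adjusted over the list alone, although the list median of 0.39 lay at percentile 100 of random lists.

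In total 353 genes were at least 2-fold higher and 120 lower in the difference of the responses. The interaction term called 396 higher and 363 lower by edgeR and 87 and 111 by DESeq2, and 652 and 526 by edgeR without Col-0 white light library 1 against 281 and 239 without low R:FR library 2. The simulated recovery of a 2-fold difference was 55% of 100 genes, so a gene outside this set is not shown to respond alike.

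**Figure D4:**
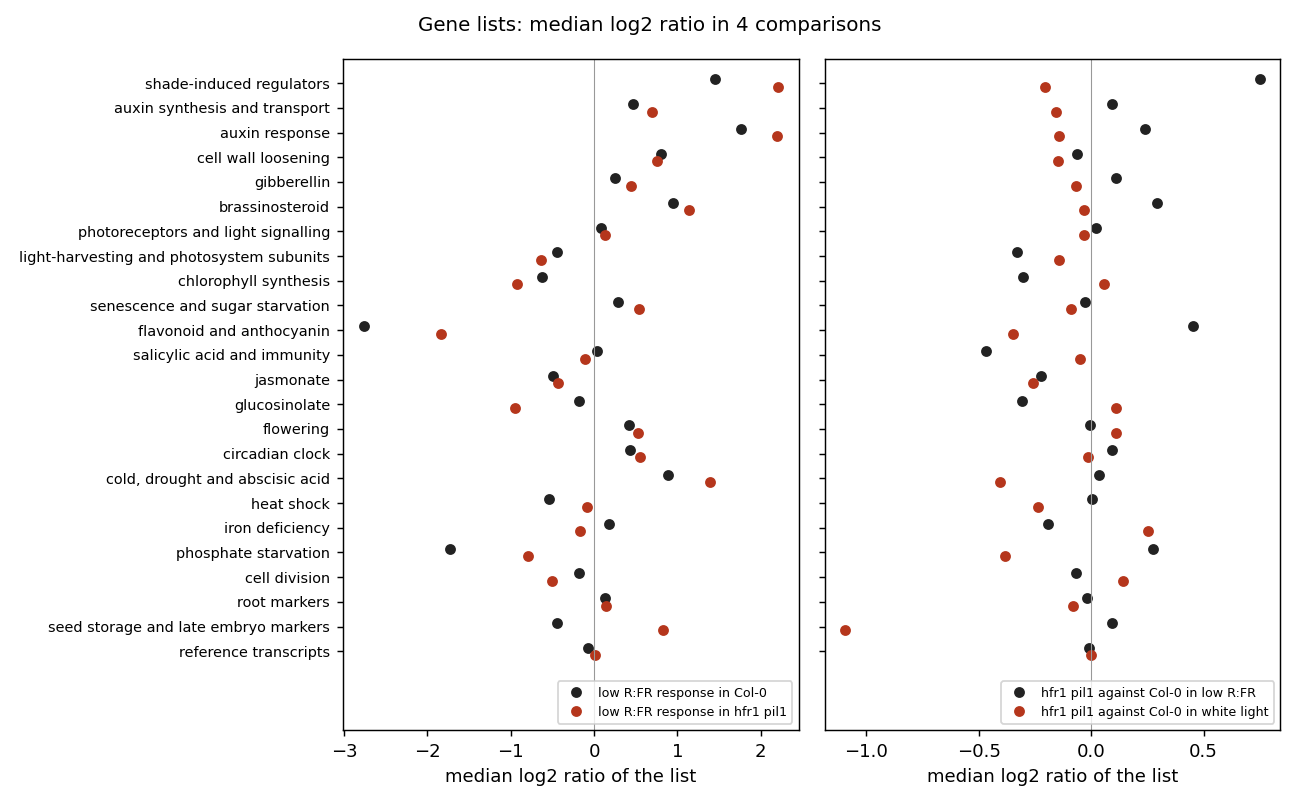
Median log2 ratio of each of the 24 gene lists, with both low R:FR responses on the left and both genotype comparisons on the right, 1 point per list and comparison and the list names on the y axis. Flavonoid and anthocyanin genes have the lowest medians of the responses (-2.77 in Col-0, -1.84 in hfr1 pil1), and shade-induced regulators are higher in hfr1 pil1 in low R:FR (0.75) but not in white light (-0.20).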

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

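All tests in this part except that on the median of the second root list were chosen after the results were seen. The edgeR fit was itself added after the data were seen. The tests for mixed-in reads, depth and close copies replaced earlier forms whose construction or choice of genes nearly fixed their outcome. The depth test still uses genes chosen for their values in the library it concerns.

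The interaction term of edgeR found a difference between genotypes in the low R:FR response of 396 genes (higher in hfr1 pil1) and 363 genes (lower). Among the ranked genes edgeR's fitted difference of the log2 responses was 2.94 for MRN1, 2.74 for CYP705A12, 2.47 for KIN1, 3.41 for M17, 2.16 for MLP328, 2.04 for CHS, 2.35 for OCT1, 1.99 for NEET and 1.94 for FSD1. On the lower side it was -2.53 for CYP79F1, -2.23 for BCAT4, -2.06 for LHCB1.4, -2.36 for BCB, -2.43 for MYB29, -1.71 for CDEF1, -1.67 for MAM1 and -1.69 for AK3. For the 2 genes of the mutant's name it was -2.87 (HFR1) and -1.27 (PIL1), and that of PIL1 was not called without Col-0 white light library 1 or low R:FR library 2 (edgeR, Benjamini-Hochberg adjusted p = 0.195 and 0.053), nor by DESeq2 (Benjamini-Hochberg adjusted p = 0.0642).

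More genes were lower than higher in the hfr1 pil1 white light library (157 against 7), the side from which several of these differences come. Root tissue evenly lower by 2-fold or more was not seen in the values of a second root list. There 0 of 20 members were 2-fold lower (log2 ratios from -0.81 to 0.32). This bound was chosen after those values were seen, so its outcome was known beforehand. In the first root list 1 of 13 markers was at least 2-fold lower. An even lack of root tissue smaller than that would by itself lower a root transcript by less than 2-fold. Whether parts of the root were lost unevenly was not tested, so the list does not settle the cause for these 157 genes. A smaller lack of root tissue stays open too. The list's median was -0.35 with 18 of 20 members (90%) below 0, short of the median set beforehand as evidence for it. PYK10, the list's most abundant gene, stood at 30068 normalized counts in Col-0 and 25173 in hfr1 pil1. The labels give shoots as the tissue, yet all 20 members passed the filter. Whether these transcripts came from shoot cells or from root left on the shoots was not tested. They also moved with light in Col-0, with log2 ratios from -4.138 for HAK5 to 2.145 for CASP5. The share of root tissue is therefore not separated from the low R:FR responses. Another sampling time may contribute, as 6 of 18 clock genes were called, 3 higher and 3 lower, although the labels give continuous light. The genotype itself is an untested biological explanation.

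HFR1 and PIL1 transcripts were higher in the hfr1 pil1 white light library than in both Col-0 white light libraries. Reads of a low R:FR library mixed into it are argued against: HFR1 would need 7.75% of such reads and PIL1 13.1%, while over 30 other genes at least 16-fold higher in low R:FR in Col-0, chosen on the Col-0 libraries alone, the median share was -0.018% for hfr1 pil1 reads and -0.024% for Col-0 reads. The share of HFR1 was reached by 2 of the 30, the highest at 14.6%. The mutations themselves and a wrong label stay open, as the table holds no read sequences.

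In the hfr1 pil1 low R:FR library edgeR called 7 of 19 glucosinolate genes lower, and the other 12 were not called. Whether lower depth of that library is the whole cause was not settled. In Col-0 white light, library 2 (7556437 reads in the genes that could be split) is shallower than library 1 (11442048). There the median log2 ratio of the same 7 genes, library 2 against library 1, was -0.21, from -0.56 to -0.077. Their log2 ratios in hfr1 pil1 to the nearer Col-0 low R:FR library lay lower than these, with a median difference of -1.09 and a range from -1.88 to -0.56. The 7 genes were chosen for being called lower in that library, which nearly fixed a gap in this direction. No conclusion on depth is drawn from it. A contribution of depth stays open, since -0.21 fell short of the bounds set for or against it. Reads shared between close copies stay open too. Over the 3 families with a called gene and at least 2 measured copies, the median log2 ratio of the summed counts was -0.36. It ran from -1.81 for CYP79F1 with CYP79F2, both called lower, to -0.086 for the MYB genes. The MYB sum cannot decide this. In Col-0 low R:FR it was 1637 normalized counts, of which MYB29 held only 75.5 and 82.3 in the 2 libraries. The median of the families is therefore not read either way, and whether their members share reads was not tested. The other called genes had no measured copy in the list. An effect of the genotype stays open as a hypothesis, with 1 mutant library.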

How the results depend on the processing

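Median-ratio rescaling and no filter (planned) kept all 13 main results of the size rule within 1.5 times, as did rescaling of nuclear genes (planned) and to the column total (chosen after seeing the data), and TMM scaling (chosen after) kept all 10 edgeR counts so. Of the 656 values of single genes and lists, 656, 644, 577 and 577 stayed the same under the first 4, with 78 moved under each of the last 2 of these. A pseudocount 0.1 times as large gave 128 higher and 183 lower genes in hfr1 pil1 against Col-0 in low R:FR, 40 and 337 in white light, and 656 and 300 for the response difference; it left 552 single values the same and moved 100. A filter at 54.2 normalized counts, with fewer genes, gave 35 lower in low R:FR, 4 higher in white light, and 234 and 69 for the difference. DESeq2 (chosen after, as all that follow) called 2294 and 2480 genes for the Col-0 response, 1626 and 1691 for hfr1 pil1, 47 and 102 in low R:FR, 17 and 92 in white light, and 87 and 111 for the difference. An edgeR call with a 2-fold change gave 216 and 71 for the difference. Single libraries thinned to 1 depth gave 101 higher in low R:FR, and 28 and 49 higher and 298 lower in white light. Leaving out 1 Col-0 library gave 6 to 40 higher and 106 to 261 lower genes in white light by size, 285 to 464 and 118 to 192 for the difference, and 50 to 78 higher in low R:FR. By edgeR it gave 146 to 324 and 187 to 462 in low R:FR, 89 to 214 and 345 to 629 in white light, and 281 to 652 and 239 to 526 for the difference. The median log2 ratio of the list iron deficiency, hfr1 pil1 against Col-0 in white light, was 0.25, ran from -0.075 to 0.65 over the left-out libraries, and reversed without Col-0 white light library 2. For these changed results the cause was not tested, apart from the smaller number of genes under the filter. No paired analysis was possible because the labels pair no samples. Depth limits the hfr1 pil1 low R:FR library most, at 7358583 reads.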

Other observations

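Clock genes differed between low R:FR and white light, although the labels give continuous light. Each light was sampled at 1 age, so another sampling time cannot be told apart from a response to the light. Of 18, 12 rose and 3 fell in Col-0 and 11 rose and 1 fell in hfr1 pil1 (edgeR, also adjusted over the list alone). PRR7 (AT5G02810) went from 243 to 899 normalized counts in Col-0 (1.90 ± 0.092 SE, edgeR, Benjamini-Hochberg adjusted p = 4.35e-09), while LHY (AT1G01060) went from 884 to 166 (-2.42 ± 0.098 SE, edgeR, Benjamini-Hochberg adjusted p = 8.82e-10). In white light 3 clock genes were higher and 3 lower in hfr1 pil1 (3 and 5 adjusted over the list alone).

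Phosphate starvation genes fell under low R:FR, all 5 measured in Col-0 and 3 in hfr1 pil1 (edgeR, also adjusted over the list alone), with PAP17 (AT3G17790), an acid phosphatase, at 601 and 167 normalized counts in Col-0 (-1.84 ± 0.10 SE). Of 14 cell division genes, 3 fell in Col-0 and 9 in hfr1 pil1, with the same counts adjusted over the list alone. Over all 20012 tested genes 5056 fell in Col-0 and 3706 in hfr1 pil1. The list median was apart from random lists in hfr1 pil1 (percentile 0.05) but not in Col-0 (5.46). Without Col-0 white light library 2 or low R:FR library 2 the Col-0 call of CYCB1;1 (-0.45) was lost (edgeR, Benjamini-Hochberg adjusted p = 0.106 and 0.164). DESeq2 did not call CYCB1;1, PCNA1 and CDKB1;1 in Col-0, nor CYCB1;1, PCNA1 and CYCD3;1 in hfr1 pil1, nor SPX1 of the phosphate list there.

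Of 6 heat shock genes, 3 fell in Col-0 (4 adjusted over the list alone) and 1 in hfr1 pil1 (1 adjusted over the list alone). The call of HSP18.2 in Col-0 (-0.61) was lost without low R:FR library 1 or 2 (edgeR, Benjamini-Hochberg adjusted p = 0.064 and 0.0517). DESeq2 did not call HSP18.2 in Col-0 or HSP90.1 in hfr1 pil1. Of 12 iron deficiency genes, 3 rose and 1 fell in Col-0, and 1 rose and 2 fell in hfr1 pil1 (edgeR, also adjusted over the list alone). The list median was not apart from random lists in either response (percentiles 94.72 and 20.17). In Col-0 the call of FRO3 (0.45) was lost without white light library 2 or low R:FR library 2 (edgeR, Benjamini-Hochberg adjusted p = 0.107 and 0.0846). FRO3 in Col-0 and BHLH100 and BHLH101 in hfr1 pil1 were not called by DESeq2. BHLH100 (AT2G41240) differed between the 2 Col-0 white light libraries, at 396 and 149 normalized counts.

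Among 7 tested reference transcripts, ACT2 (AT3G18780) rose in Col-0 from 5484 to 9391 normalized counts (0.78 ± 0.065 SE, edgeR, Benjamini-Hochberg adjusted p = 6.21e-07) and in hfr1 pil1 (0.55 ± 0.093 SE, edgeR, Benjamini-Hochberg adjusted p = 0.000465). UBC21 also rose in Col-0 (0.26), and these counts were the same adjusted over the list alone. The median over all 10 was -0.069 in Col-0 and 0.060 with columns rescaled to their total, so its sign rests on the scaling. The same rescaling turned the median of the salicylic acid list in hfr1 pil1 from -0.11 to 0.036.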
